A study of Mus musculus with 15 samples.

How the data were processed

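Total RNA from frozen triceps muscle of a mouse model of GNE myopathy (15 samples) was labelled with biotin and hybridised to 1-colour expression arrays. Per the labels' protocols, RNA was taken from cryostat sections, 1 microgram was reverse-transcribed from oligo-dT primers, and biotin-labelled cRNA was made by in vitro transcription. The platform, the scanner software, the background correction, the genome build and the annotation are not given in the sources used here.

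The deposited values are linear intensities, 1 for each of 36227 features on each of 15 arrays. They had been normalized between arrays by the authors before deposit, as the values themselves show: after each array was sorted, 99.4% of the ranks agreed within 1% over the 15 arrays, and each array had a highest value of 22476. The lowest deposited intensity is 0.001, called the floor here. How a value came to be set to 0.001 is not given in the sources used here. Because the arrays were brought to 1 distribution, a general rise or fall of all transcripts could not be seen. The arrays' number, not a read depth, limits the precision.

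The deposited table numbers its features from 1 to 36227 and pairs none with a probe or a gene. No gene could therefore be named, and features are given by number. The 40 gene lists fixed before the data were examined, the Gne gene itself, the choice of 1 probe per gene and the check of the animals' sex needed gene names and were not run. Each feature was tested on its own in place of 1 probe per gene. No genomic position is given for the same reason.

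Intensities were turned into log2(value + 16), so a log2 difference understates the change of dim features. The arrays' medians on this scale spanned 0.000144, under the limit of 0.3 set in advance for a further normalization, so the deposited scaling was kept. The 6 arrays of N-acetylcysteine-treated mice (NAC) were compared with the 9 arrays of untreated mice in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a trend of the spread on brightness), without covariates. Benjamini-Hochberg adjustment was over all 36227 features, and a feature was called at an adjusted p under 0.05. All log2 differences are NAC minus untreated. The slope per week of treatment was fitted in the same way over the 6 NAC arrays.

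Features were named by a rule fixed before the data were examined: the largest rises and falls among called features whose higher group mean reached the median brightness. Since no gene names were at hand, only 2 features in each direction are named, and features with a floor value on any array were left out of this ranking because such values have no order. The labels do not say whether samples came from separate animals, although each has its own number in its title. P-values measure the spread between these samples.

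Arrays were compared by Spearman correlation over all features. The place of an array between the groups was computed over the 33880 features without a floor value, with that array left out of its group's mean; 0 is the mean of its own group and 1 the mean of the other. The spread of each array about its group mean was compared by an exact two-sided permutation test, where exact means that all splits were used. The group means were not recomputed for each split, so the p is approximate for a difference in spread. Features were also summarised in blocks of 1000 consecutive numbers. The test was checked on simulated data with the real features' means and spreads over 36227 features. Of 50 features changed in each class, it recovered 30% at 1.25-fold, 74% at 1.5-fold, 98% at 2-fold and 100% at 3-fold. It made 9 false calls beside 200 changed features and 0 calls with none changed. These folds are on the scale with the pseudocount added, where a dim feature needs a larger change in intensity to reach them. For dim features the rates therefore do not hold for the same folds in intensity. The simulated noise was independent between features and arrays. These rates therefore do not cover deviations shared by many features on an array, such as those along the feature numbers.

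Alternatives fixed in advance were quantile normalization, centring on array medians, leaving out features below the median brightness, a fit without the trend, array weights, pseudocounts of 1 and 64, a Welch test per feature with Benjamini-Hochberg adjustment, and leaving out each array. Alternatives on floor values and on a deviation along the feature numbers were added after the data were seen.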

Results

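Gene expression was measured in triceps muscle of mice that lack the endogenous Gne gene and carry a mutant GNE transgene. GNE encodes the bifunctional enzyme that starts the synthesis of sialic acid, and its mutations cause GNE myopathy, a recessive muscle disease. The 15 arrays fell into 9 from untreated mice and 6 from mice that had been given 1% N-acetylcysteine, an antioxidant and precursor of cysteine, in their drinking water. There were no arrays from healthy mice among them, so the comparison is of treated with untreated model mice. The series set out to find disease mechanisms and the pathways that respond to N-acetylcysteine. All 9 untreated samples, and none of the NAC samples, carry the word reanalysis in their titles. The deposited intensities had a median of 20.8 and a highest value of 22476 on each array, and each array listed between 246 and 401 of its 36227 features at the floor of 0.001.

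The arrays of the groups differed over the whole profile. Pairs of NAC arrays correlated with a median Spearman coefficient of 0.949 (15 pairs, range 0.943 to 0.958), pairs of untreated arrays with 0.933 (36 pairs, 0.910 to 0.944), and pairs across groups with 0.912 (54 pairs, 0.893 to 0.939). The first principal component held 28.9% of the variance over the features without a floor value. Untreated replicate 1 was as close to the NAC arrays as to its own group. Its mean correlation was 0.936 with the other untreated arrays and 0.936 with the NAC arrays. The other 8 untreated arrays reached between 0.899 and 0.914 with the NAC arrays. Replicate 1 was not remote from its own group, since the other untreated arrays had 0.923 to 0.936 with their own group. On a scale from 0 at the mean of the other untreated arrays to 1 at the NAC mean, untreated replicate 1 lay at 0.622. The others lay between -0.310 and 0.209. The NAC arrays were also more alike. The spread of an array about its group mean was 0.180 ± 0.00883 on the log2 scale (SD, n = 6) in NAC and 0.213 ± 0.0280 (SD, n = 9) in untreated samples, an exact two-sided permutation p of 0.0158 over 5005 splits. Without untreated replicate 1 this exact p was 0.0186. Both p-values are approximate, because the splits regrouped fixed spreads without new group means.

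**Figure D1:**
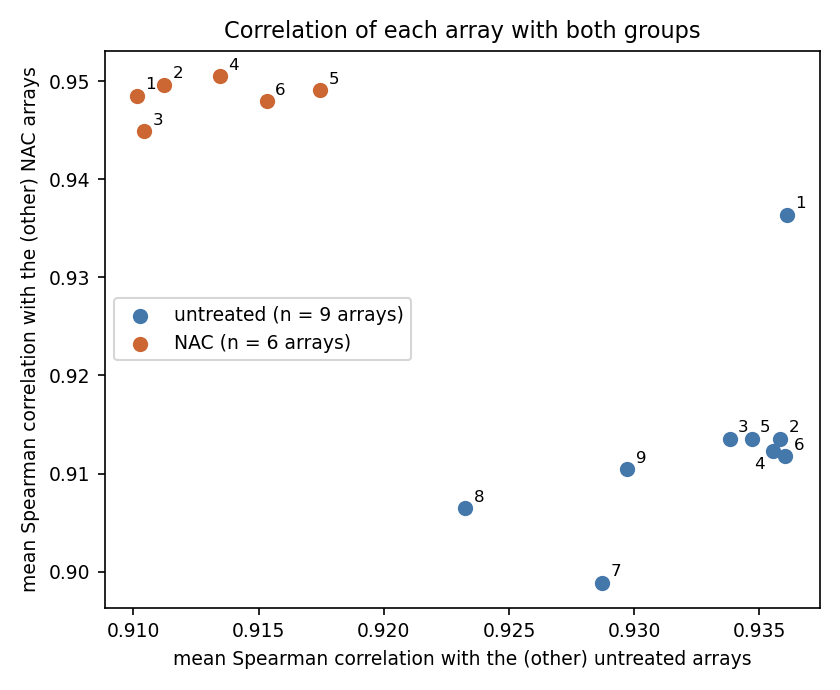
Mean Spearman correlation of each array with the untreated arrays (x axis) and with the NAC arrays (y axis), leaving out the array itself; numbers are replicates. Untreated replicate 1 has 0.936 with the NAC arrays, above the other 8 untreated arrays, which lie between 0.899 and 0.914.

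N-acetylcysteine treatment was the contrast the design was made for. Of 36227 features, 5536 (15.3%) differed between NAC and untreated samples in limma's test at an adjusted p under 0.05: 2643 were higher and 2893 lower in NAC. Most differences were small on the log2(value + 16) scale, which understates the change of dim features. Among the 5225 called features without a floor value, the median difference was 1.29-fold on that scale, which also sets the classes that follow. Of these, 825 differed by under 1.2-fold, 3819 by 1.2-fold to 1.5-fold, 512 by 1.5-fold to 2-fold and 69 by at least 2-fold (20 higher and 49 lower in NAC). Leaving out untreated replicate 1, whose profile lay between the groups, gave 6480 calls. With the deviation of 5 feature blocks as a covariate, an alternative added after the data were seen, 1302 were left (657 higher and 645 lower in NAC); the same deviations shuffled within groups left a median of 2627.5. The treatment groups coincide with the wording of the titles and with the floor pattern described next, so a difference between sets of arrays and a difference between treatments cannot be told apart in this design.

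Among called features without a floor value, feature 30511 had the highest log2 difference on the log2(value + 16) scale. Its intensity was 12.2 ± 4.25 (SD, n = 9) in untreated and 126 ± 13.2 (SD, n = 6) in NAC samples, a log2 difference of 2.34 with a standard error of 0.0968 and an adjusted p of 3.96e-13 in limma's test. Feature 34311 followed, with 24.9 ± 5.66 (SD, n = 9) in untreated and 149 ± 8.43 (SD, n = 6) in NAC samples, a log2 difference of 2.03 ± 0.0865 (SE) and a limma adjusted p of 6.46e-13. For both, the lowest NAC value (112 and 138) lay well above the highest untreated value (19.3 and 35.8), and untreated replicate 1 (19.3 and 19.2) lay with its own group. The untreated level of feature 30511 lay below the array median of 20.8 and is not shown to be above background, so the size of its difference is uncertain. The pseudocount set the size of both: with 64 in place of 16 the log2 differences were 1.32 and 1.26, with 1 they were 3.33 and 2.57. Feature 16925 fell from 259 ± 181 (SD, n = 9) to 53.8 ± 28.8 (SD, n = 6), a log2 difference of -1.87 with a standard error of 0.359 and a limma adjusted p of 0.00229. Feature 21056 fell from 323 ± 294 (SD, n = 9) to 61.6 ± 18.4 (SD, n = 6), a log2 difference of -1.78 with a standard error of 0.374 and a limma adjusted p of 0.00413; with the deviation of 5 feature blocks as a covariate, an alternative added after the data were seen, it was -1.27 with an adjusted p of 0.0934 and the call was lost. Which of these 2 falls was larger changed with the setting: without untreated replicate 1 the log2 differences were -1.80 for feature 16925 and -1.95 for feature 21056. The falls rested on widely scattered untreated arrays, and the groups overlapped. Feature 16925 ranged from 73.3 to 690 in untreated and from 17.1 to 81.8 in NAC samples. Feature 21056 ranged from 88.9 to 1026 in untreated and from 44.0 to 95.1 in NAC samples, and untreated replicate 1 had the 88.9. The genes behind these 4 features are not named, because the files do not pair feature numbers with genes.

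**Figure D2:**
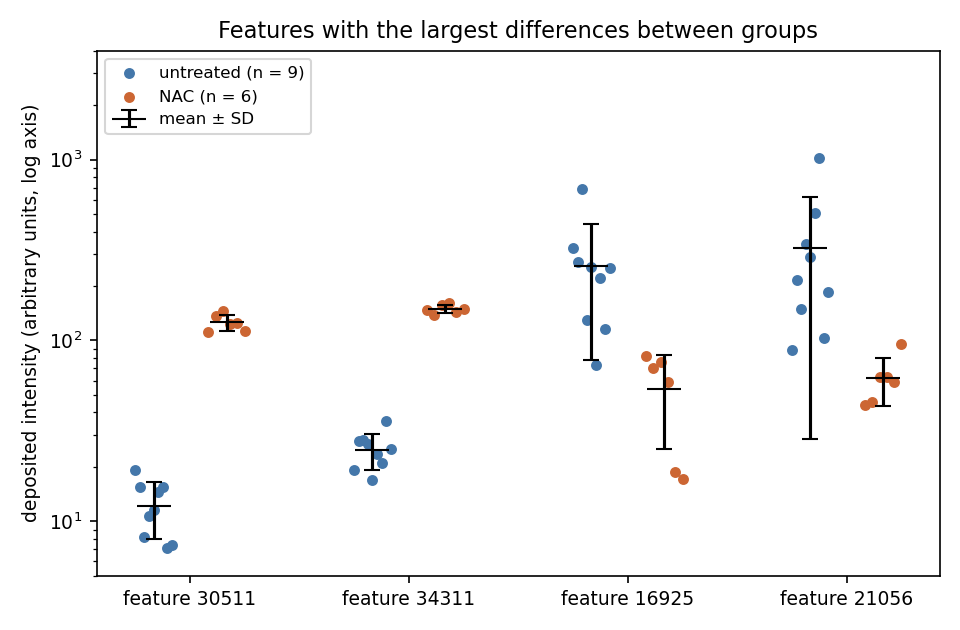
Deposited intensity (log axis, arbitrary units) of the 4 named features on each array; points are arrays, bars the mean ± SD of 9 untreated and 6 NAC arrays. Features 30511 and 34311 separate the groups completely, whereas the untreated values of features 16925 and 21056 scatter widely and overlap those of NAC.

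A separate class of features was listed at the floor on a whole group. On all 9 untreated arrays and on no NAC array, 129 features had the value 0.001; on all 6 NAC arrays and no untreated array, 118 features did. In the group where they were measured, their median intensities were 23.7 and 23.3, close to the array median of 20.8, and their highest were 1764 and 4737. All 247 were among the called features. Their selection all but fixed this, since 1 group had no spread and the other had no floor value. The 247 features made up 149 of the 222 calls with at least a 2-fold difference (76 higher and 73 lower in NAC). The pseudocount sets the difference of a feature at the floor, so the 149 and the 222 hold for a pseudocount of 16 only; with 1 there were 677 calls of at least 2-fold in all, and with 64 there were 88. No fold is given for single features of this class. Another 2100 features had a floor value on some arrays; for 2072 of them this was on 1 or 2 arrays, and 2 features had it on all 15.

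Calls were unevenly distributed over brightness and over the feature numbers. With the features without a floor value ranked by mean intensity into 3 equal classes, 334 of 11294 (2.96%) were called in the dimmest class, 1866 of 11293 (16.5%) in the middle class and 3025 of 11293 (26.8%) in the brightest class. The brightest class had 1454 features higher and 1571 lower in NAC, the middle class 846 and 1020. Along the numbers, the 4 blocks from 26001 to 30000 had the highest shares of features called higher in NAC. In the block from 27001 to 28000, 176 of 938 features (18.8%) were called higher in NAC and 42 (4.48%) lower; in the first 1000 features these shares were 3.73% and 6.93%. The highest share of rises in any block was 13.9% over 1000 random orders of the features, against 18.8% in the real order. The blocks compared include the last one, with 216 features, where shares scatter more by chance than in the block from 27001 to 28000.

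**Figure D3:**
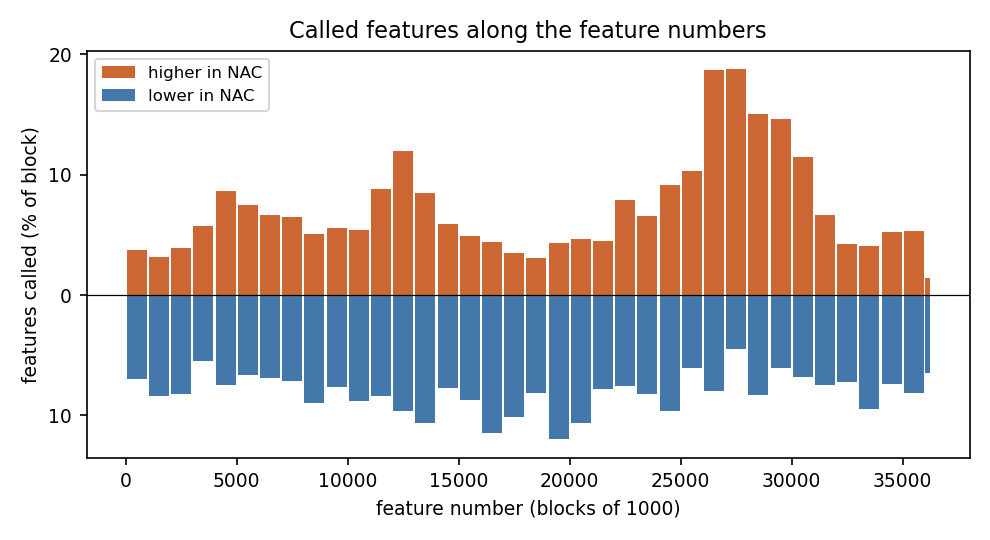
Share of features called higher (up) or lower (down) in NAC, in percent of the features without a floor value, in blocks of 1000 consecutive feature numbers. Rises reach 18.8% in the block from 27001 to 28000, against 3.73% in the first block.

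The labels give each NAC sample its own treatment time, from 30 to 35 weeks in steps of 1 week that follow the order of the samples, so treatment time cannot be separated from sample order. Whether these are the true durations could not be checked, and a slope per week has a meaning only if they are. No feature changed with time by limma's test over these 6 arrays (0 of 36227 called, lowest adjusted p of 0.376). The unadjusted p of limma's slope test was under 0.05 for 2257 features (6.23%), 1015 rising and 1242 falling. That share is little above what a limit of 0.05 passes by chance, so it does not show slopes. The median standard error of a slope was 0.0323 on the log2 scale per week, so gradual changes of this size were not detectable with 1 array per time.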

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

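The tests of the floor pattern, of mislabelling, of the array sets, of kinds of difference and of the size kept with a covariate were chosen after the results were seen. Of 18 sets of array values examined for a single outlying array, 3 had one; chance gives about 5% of sets. Untreated replicate 1 had a mean correlation of 0.936 with the NAC arrays, against 0.914 for the nearest other untreated array. Untreated replicate 9 had 272 floor values outside the group-wide class, against 193 for the next. NAC replicate 1 had 158, against 143.

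Untreated replicate 1 lay at 0.622 of the way to the NAC arrays, while the other untreated arrays lay between -0.310 and 0.209. The outlier test was also run on this place and flagged no array. Of the 130 features at the floor on all other untreated arrays, 129 were at the floor here, and 0 of the 118 of the NAC pattern. This would argue against an array of the NAC set filed under the untreated label if the floor came with the arrays. How values came to be 0.001 is not given, and they may have been set by label, so the floor pattern cannot decide this. A restriction to 1 range of brightness is argued against, since the array lay above all other untreated arrays in each of 3 brightness classes. Its lowest place was 0.581, in the brightest class. In the dimmest class it lay at 0.619 and another untreated array at 0.396. A treated sample under an untreated label stays open, because part of the group difference may belong to the array sets, and so does a natural difference among untreated mice, which was not tested. With this array left out of the group means, the features without a floor value and with at least a 2-fold difference lay nearer the untreated arrays on it in 5 of 5 cases at 8 SD or more, 3 of 12 at 4 to 8 SD and 18 of 82 under 4 SD (Fisher's exact p = 0.00092 for the first set against the rest, the limit chosen after the values were seen), but picking features with little spread among untreated arrays favours this, 1 of the 5 lay at the limit (8.03 SD, place 0.493), and no second kind of group difference can be read from it.

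The 247 features at the floor on exactly 1 group of arrays may be spots that were missing or masked in 1 set of arrays. In the group that measured them, 55.1% lay at or above the array median (exact 95% binomial interval 48.6 to 61.4%), much as features at large would. Chance dropout of dim transcripts on single arrays is argued against, since it would leave many features at the floor on only part of a group. Only 8 features were at the floor on most but not all arrays of a group (4 to 5 of the NAC or 6 to 8 of the untreated arrays). Floor values set by label would leave no such features either. Transcripts close to the floor in a whole group therefore stay open.

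The 5536 calls are beyond chance splits: in 100 of the 5005 splits of the arrays, the real one included, 1 gave as many, and the highest other count was 3. Whether treatment or the set of arrays made them cannot be told apart, since the treatment groups coincide with the wording of the titles. That 0 arrays carry the other group's floor pattern follows from how that pattern was defined, so this count decides nothing. A median deviation was taken on each array over the 5 blocks of 1000 feature numbers with most calls higher in NAC (26001 to 30000 and 12001 to 13000). With this deviation as a covariate 1302 features were called, but the same deviations shuffled within groups left a median of 2627.5 calls (992 to 4340 over 50 shuffles), so that drop decides nothing. Outside the blocks, the 4147 called features kept 88.6% of their difference and all kept their sign, while the median standard error grew from 0.0886 to 0.107. The measured deviation thus took away little of the differences of these features. They were picked as called, which favours features with little spread within groups, and the share kept with shuffled deviations was not computed. Whether the deviation was the whole cause is therefore not decided.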

How the results depend on the processing

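The count of called features (5536) stayed within 1.5 times under all alternatives except 1 added after the data were seen: with the deviation of 5 feature blocks as a covariate it was 1302 (657 higher, 645 lower in NAC), and feature 21056 then had a log2 difference of -1.27 with a limma adjusted p of 0.0934. The highest count was 6775, with array weights. Leaving out each array gave 4175 to 6480 calls, 2001 to 3169 of them higher and 2174 to 3311 lower, and 208 to 248 with at least a 2-fold difference. The 222 calls with at least a 2-fold difference moved by over 1.5 times in 5 settings: 137 without the features below the median brightness, 677 with a pseudocount of 1, 88 with a pseudocount of 64, 69 without features with a floor value and 73 without those at the floor on a whole group. The pseudocount sets the fold scale and the other 3 settings remove features. Calls higher in NAC made up 42.7% to 50.5% of the calls over all settings, 47.7% in the main one. Features 30511, 34311 and 16925 kept direction and call throughout, with log2 differences of 1.32 to 3.33, 1.26 to 2.57 and -2.23 to -1.33 and adjusted p up to 2.9e-09, 2.07e-08 and 0.0125; feature 21056 kept its direction, with adjusted p from 0.00095 to 0.0934. The spread of the NAC arrays stayed below that of the untreated arrays in each setting run (exact p from 0.0034 to 0.035), and the place of untreated replicate 1 ranged from 0.594 to 0.623. The slope with treatment time called 0 features in each setting run, leaving out each NAC array included. The probe rules, the Xist covariate, the gene lists and the test of Gne were not run, because the features have no gene names. The number of arrays and the unknown background level limit what can be said of dim features.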

Other observations

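The 5 blocks of feature numbers richest in calls higher in NAC did not move with treatment alone; this was looked at after the result was seen. Their median deviation from the mean of all arrays, relative to the other features, was between 0.0213 and 0.109 on the log2 scale on NAC replicates 1 to 4. It was -0.0507 on NAC replicate 5 and -0.00113 on NAC replicate 6. Untreated replicate 1 had 0.0499, and the other 8 untreated arrays lay between -0.0708 and -4.0e-05. What the feature numbers stand for on the array is not given in the sources used here.

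Of the called features without a floor value, the dimmest of 3 brightness classes held 175 higher and 159 lower in NAC. Their median absolute log2 difference was 0.32, against 0.37 in the brightest class. Both were taken after the pseudocount was added, which understates the change of dim features. The median mean intensity was 6.7 in the dimmest class and 111 in the brightest. These sizes therefore do not show that dim features changed less in intensity.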
